A study of Homo sapiens with 6 samples.

How the data were processed

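RNA-seq was done on LX2 cells, an established human hepatic stellate cell line, after lentiviral expression of a short hairpin RNA. Per the labels, 6 libraries fall into 3 groups of 2: shLuc (a control hairpin against firefly luciferase), shMETTL3-1 and shMETTL3-2, which carry 2 different hairpins against METTL3 in the pLKO.1 vector. Per the labels, the virus was made in HEK293T cells (a human embryonic kidney line), cells were grown in high-glucose DMEM with 10% serum, exposed to virus for 10 h with 1 µg/ml polybrene, and selected with 1 µg/ml puromycin. Total RNA was extracted with Trizol and reads were mapped to hg19, per the labels. DESeq2 is named without a role or version in the submitters' processing notes, and the labels also mention gene set enrichment software. The aligner, counting tool, gene filter, annotation release and library selection are not given in the sources used here.

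The deposited table lists 12654 genes with 1 value per library, an Ensembl gene, 1 transcript and its hg19 position. It is called a count matrix, but the values do not behave as raw counts, so each deposited value is treated here as a score. Column totals run from 16535130 to 16536605, and each column has the same maximum of 72566 and the same median of 552. After sorting, 87.3% of ranks hold an identical value in all 6 libraries, and the largest difference at any rank is 8. A score is therefore close to a rank mapped to a common set of values. Sequencing depth is not kept, counting error cannot be computed, a shift of all genes together would not be seen, and no depth per library can be given.

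This has 2 further effects. In each library 10 genes share the maximum, 18 genes reach it in at least 1 library, and a change among these genes is truncated. Below the maximum, too, the highest scores are each shared by several genes, so their folds move in steps. Replicates can then tie, and a small SE among such genes is not a measured precision. Ties within a group occur below for, among other genes, COL5A1, SPARC, FTL, LOXL2, PGK1, CTGF, PCNA, CNN2, TPM1, SERPINH1, MKI67, EPAS1 and HK2. At the low end 202 genes are listed at 0 in at least 1 library, and they often stand well above 0 in the replicate. Among tested genes whose lowest value is 0, the median of the larger replicate difference is 7.5 on the log2 scale (141 genes), against 0.15 where the lowest value is 100 or more (10107 genes).

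Genes with a mean score of at least 50 were tested (12413 genes; 241 were left out). The log2 of the score plus a pseudocount of 1 was fitted by limma 3.58.1 in R 4.3.3, with 1 mean per group, a mean-variance trend and robust empirical Bayes moderation. All 6 libraries shared 1 estimate of the spread, with 3 residual degrees of freedom before moderation. Fold changes are on this log2(score + 1) scale. The contrasts were each hairpin against shLuc, the mean of both hairpins against shLuc, and shMETTL3-2 against shMETTL3-1. P-values are two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. A gene counted for both hairpins had to be called with each of them in the same direction. No source says that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

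The 37 gene lists, the contrasts, the rule for named genes and most alternatives were fixed before the data were examined. Of the lists, 33 had at least 5 tested members and were tested with camera (preset inter-gene correlation 0.01), adjusted over the lists within a contrast. Each test was repeated with an estimated correlation and with fry. With an estimated correlation camera has only the 3 residual degrees of freedom of the fit, so it has little power here. A list that does not pass it is neither established nor ruled out by that test. Camera compares a list with the other genes, whereas fry tests whether the genes of a list move, on balance, in one direction, without comparing them with other genes. The scheme fixed in advance called for a count model with its own scaling and filter. Neither edgeR nor DESeq2 was run, since the values are not counts, and no scaling was applied because the columns already share 1 distribution.

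Named genes are METTL3 and 15 others chosen in advance, the 10 largest rises and falls shared by both hairpins, the 5 largest in each direction for each hairpin and for their difference, and up to 4 members of each of 21 lists. The rule asked for a minimum CPM, which was replaced by the mean score of 50. Applied as written, it fills 50 places with 36 genes, and in 44 of these places the gene has a value under 10 in some library. For the ranking, genes with any value under 10 were therefore passed over. This limit was chosen after the values were seen, it removes genes that fell to the floor or rose from it, among them genes with larger fitted changes than those ranked, and only 6 places are shared between the 2 versions. Genes picked by the rule as written that have a value under 10 are given as listed scores without folds. The results of 1 list, with the genes named only through it, and of 1 member of another list are not reported here, though counts of lists and genes include them.

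The fitting steps were tested on simulated data for the comparison of shMETTL3-1 with shLuc over 12413 genes. Changes of 0.5, 1 and 2 on the log2 scale were recovered for 71.6%, 92.5% and 98.5% of the changed genes. These were 48 of 67, 62 of 67 and 65 of 66 genes. Of the unchanged genes 20 (0.16%) were called. Beside the recovered genes, these 20 are a larger share of all calls than the adjusted p threshold allows on average. In this simulation false calls were thus more frequent than that threshold states. A simulated shift of 0.3 in 1 list of 63 genes was called and 0 other lists were. The simulated genes varied independently of each other, so this does not test list calls where genes are correlated. Their values were drawn with normal error, without ties or a maximum, and few genes were changed. Calls on tied or truncated scores, or with most genes changed, were therefore not tested. Because both hairpin contrasts use the same shLuc libraries, 50 simulations of unchanged hairpin groups against shared controls gave the values set beside the overlap. Gene identifiers were matched to the GENCODE annotation of GRCh37 for GC content and transcript length (98.2% of identifiers matched). Both were taken from the longest annotated transcript of each gene, which need not be the listed one. Of the listed transcripts found there, 47.5% had the same start and end, and the positions given are those of the deposited table. In 19 places a date stood where a symbol should be, and the symbol was recovered from the Ensembl identifier.

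Alternatives were median-of-ratios scaling, no filter on low values, voom weights, a replicate block, only the groups compared, both hairpins as one group, a 2-fold threshold, and leaving out each library in turn. Added after seeing the data were pseudocounts of 10 and 50 and leaving out genes with a value under 10 or genes at the maximum. Removing a trend on transcript length (loess, span 0.5) was added then too. Lost calls and ranges given for single genes and lists do not cover the fit with both hairpins as one group. For lists they also leave out voom weights, only the groups compared, the estimated correlation and fry. Data were handled with the R packages data.table (version 1.17.8) and igraph 2.1.4, with pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9 in Python 3.11.15.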

Results

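Gene expression was measured by RNA-seq in LX2 cells, a line of human hepatic stellate cells, the liver cells that turn into matrix-producing myofibroblasts in fibrosis. Cells carried a control hairpin (shLuc) or 1 of 2 hairpins against METTL3, the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on RNA. Each of the 3 groups had 2 libraries. By the series title, the question was how loss of METTL3 affects stellate cell activation. The scores share 1 distribution in all libraries, with a median of 552 and a maximum of 72566, so depth per library is unknown. Replicates differed by a median of 0.08 to 0.10 on the log2 scale per gene, and libraries of different groups by 0.36 to 0.41. The first principal component (39.3% of the variance) set shMETTL3-2 apart from the other groups, and the second (34.6%) set shLuc apart from shMETTL3-1.

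METTL3 (ENSG00000165819, chromosome 14, 21966277 to 21971972 in hg19, minus strand) was lower with both hairpins. It scored 536 and 552 with shLuc, 274 and 256 with shMETTL3-1, and 148 and 132 with shMETTL3-2. The means were 544 ± 11.3, 265 ± 12.7 and 140 ± 11.3 (SD, n = 2). The score was 2.05-fold lower with shMETTL3-1 (adjusted p = 0.000107) and 3.87-fold lower with shMETTL3-2 (adjusted p = 6.44e-06). The 2 hairpins differed by a log2 change of -0.92 (SE 0.10, adjusted p = 0.00016), and their mean lay at -1.49 (SE 0.09, adjusted p = 1.18e-05).

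Among the other 10 tested subunits of the m6A writer complex and related methyltransferases, RBM15B, an RNA-binding adaptor of the complex, rose with both hairpins (log2 0.53 and 0.96). CBLL1, which the rule for named genes did not pick, was also called higher with both (0.515 and 0.236). KIAA1429, a scaffold also known as VIRMA, rose with shMETTL3-1 (0.73), while its log2 change with shMETTL3-2 was -0.11 (adjusted p = 0.172); the hairpins differed by -0.84 (adjusted p = 3.38e-05). ZC3H13, which anchors the complex in the nucleus, fell in the mean of both hairpins (log2 -0.26, adjusted p = 0.0146). That call was lost without shLuc replicate 1 (log2 -0.27), shLuc replicate 2 (-0.25) or shMETTL3-1 replicate 2 (-0.22). METTL14, the partner of METTL3, had a log2 change of 0.26 in the mean (adjusted p = 0.107), which passed without shLuc replicate 1 (0.46, adjusted p = 0.0148; range 0.0148 to 0.703). It was called higher with shMETTL3-1 (0.42, adjusted p = 0.0337) and lay at 0.09 with shMETTL3-2 (adjusted p = 0.61), and the hairpins did not differ past the threshold (adjusted p = 0.0712). WTAP, the regulatory subunit, changed by 0.07 (adjusted p = 0.202). Of the 11 tested members in the mean, 3 were higher, 2 lower and 6 did not pass, with 3 and 2 adjusted over the list alone. The list did not pass camera (adjusted p = 0.68, and adjusted p = 0.735 with an estimated correlation).

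**Figure D1:**
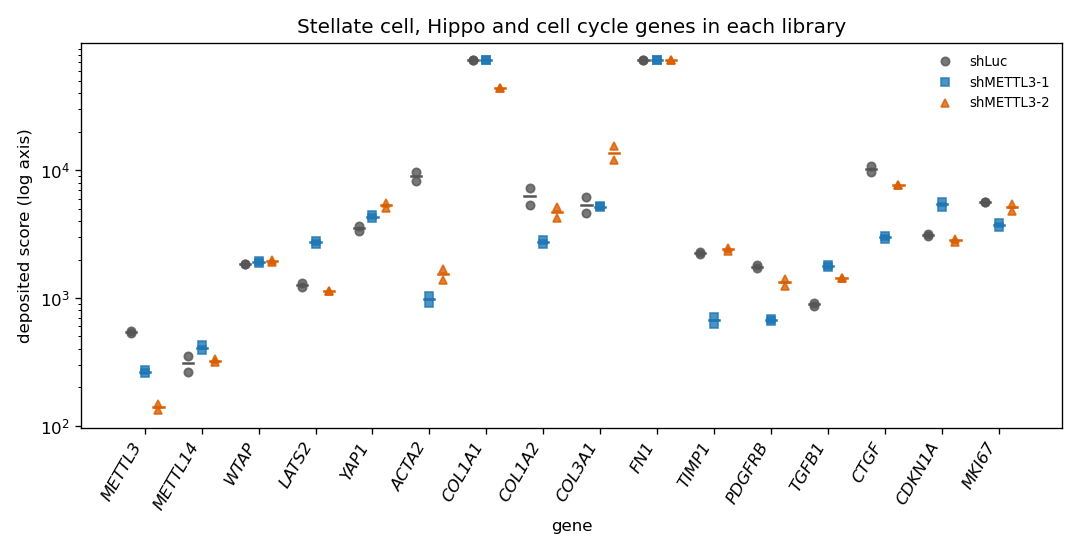
Deposited score on a log axis for 16 genes chosen in advance, with 1 point per library, 2 libraries per group and a line at each group mean. METTL3 stood at 544, 265 and 140 in shLuc, shMETTL3-1 and shMETTL3-2, ACTA2 at 8990, 979 and 1544, and FN1 stayed at the shared maximum of 72566 in every library.

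The mean of both hairpins against shLuc asks what changed on average over the 2 hairpins. A gene changed by 1 hairpin alone can be called in it. The rankings of single genes in this and the other contrasts leave out genes with a value under 10 in any library, whose listed scores are given last. Among the rest, CLDN1, a tight junction protein, rose most of the genes changed by both hairpins. Its score was 28 in both shLuc libraries, 654 and 737 with shMETTL3-1, and 946 and 986 with shMETTL3-2 (chromosome 3, 190023490 to 190040264; log2 4.82, SE 0.08, adjusted p = 2.99e-07). MMP1, interstitial collagenase, rose by a log2 of 4.62, and HMGA2, a chromatin architectural protein, by 4.15. LCP1, an actin-bundling protein, rose by 3.77, SUMF1, which activates sulfatases, by 3.46, and CAV2, a caveolar protein, by 3.40. The other large rises were PTPRB, a receptor tyrosine phosphatase, at 3.21, EMB, a cell adhesion glycoprotein, at 3.19, CHIC1 at 2.99, and DOCK4, an activator of small GTPases, at 2.93.

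MAMDC2, a secreted matrix-associated protein, fell most among the ranked genes. Its score went from 6239 and 7376 to 31 and 40 with shMETTL3-1 and to 916 and 1048 with shMETTL3-2 (chromosome 9, 72658497 to 72841886; log2 -5.17, SE 0.12, adjusted p = 9.94e-07). TNC, the matrix glycoprotein tenascin-C, fell from the shared maximum in both shLuc libraries to 3266 and 3311 with shMETTL3-1 and 7093 and 9719 with shMETTL3-2, so its log2 change of -3.80 is truncated. Other falls were in SYNPO2, an actin-binding protein (-3.67), ACTG2, smooth muscle gamma actin (-3.61), and LMOD1, an actin nucleator (-3.26). NPPB, the natriuretic peptide precursor, fell by 3.65 on the log2 scale. The remaining large falls were AIF1L at -3.66, the integrin subunit ITGB3 at -3.55, PITPNM3 at -3.52 and the microtubule protein MAP6 at -3.15.

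In this comparison 7237 of 12413 genes (58.3%) were called, 3666 higher and 3571 lower, with adjusted p from limma and 2 libraries per group. Counts of list members called in the mean are to be read beside this share of all genes. With both hairpins treated as one group of libraries, the difference between hairpins enters the spread and 1494 genes were called, 841 of them higher. Of the genes named for the mean, 56 lost their call in that fit and 55 stayed on the same side of the threshold, among them METTL14, WTAP and FN1, which were not called in either fit. METTL3 had an adjusted p of 0.0496.

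Of the genes chosen in advance for stellate cell activation, ACTA2 (alpha smooth muscle actin, the usual marker of activated stellate cells; chromosome 10, 90694831 to 90712530) fell with both hairpins. It scored 8266 and 9713 with shLuc, 917 and 1040 with shMETTL3-1, and 1394 and 1694 with shMETTL3-2, a fall of 9.17-fold and 5.83-fold (adjusted p = 4.83e-06 and 1.07e-05). PDGFRB, the receptor for platelet-derived growth factor, also fell with both, by log2 -1.40 and -0.41. TIMP1, an inhibitor of metalloproteinases, fell with shMETTL3-1 (-1.76) but had a log2 change of 0.09 with shMETTL3-2 (adjusted p = 0.282). Among collagens, COL1A2 fell with shMETTL3-1 (-1.18) and lay at -0.40 with shMETTL3-2 (adjusted p = 0.0864), while COL3A1 rose with shMETTL3-2 (1.36) and lay at -0.04 with shMETTL3-1 (adjusted p = 0.883). The hairpins differed for TIMP1 (log2 1.85 higher with shMETTL3-2, adjusted p = 1.72e-06), COL1A2 (0.78, adjusted p = 0.00899) and COL3A1 (1.40, adjusted p = 0.000761). COL1A1 stood at the maximum of 72566 in the shLuc and shMETTL3-1 libraries and at 44454 in both shMETTL3-2 libraries, and FN1, fibronectin, stood at the maximum in all 6, so neither gives a measured fold. TGFB1, the main profibrotic cytokine, rose with both hairpins (1.00 and 0.69).

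The contractile genes of myofibroblasts fell as a group. Of 25 tested in the mean of both hairpins, 21 were lower, 2 higher and 2 did not pass, with the same counts of 21 and 2 adjusted over the list alone. Camera gave an adjusted p of 7.04e-07 for the list (adjusted p = 0.213 with an estimated correlation). Besides ACTG2 and LMOD1 among the falls, the 2 that rose were CNN2, a calponin (log2 1.08), and TPM1, a tropomyosin (0.26, adjusted p = 0.0111). TPM1 did not pass without shLuc replicate 2 (log2 0.205). With both hairpins 17 members were lower and 1 higher, and 0 were called in opposite directions.

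Matrix glycoproteins were lower in the mean. Of 36 tested, 19 were lower, 9 higher and 8 did not pass, or 20 and 9 adjusted over the list alone. The list had an adjusted camera p of 0.0301 (adjusted p = 0.422 with an estimated correlation). SDC4, a cell surface heparan sulfate proteoglycan, fell by 2.16 on the log2 scale beside TNC, whereas SPARC, a collagen-binding glycoprotein (1.52), and EFEMP1, a fibulin (1.80), rose. With a trend on transcript length removed, an alternative chosen after seeing the data, the list did not pass (0.0607; range 0.021 to 0.0607). With shMETTL3-1 alone 8 were higher and 15 lower, and the list did not pass (adjusted p = 0.445).

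Collagen chains went both ways: 7 of 19 were higher, 9 lower and 3 did not pass, equal to the counts adjusted over the list alone. COL6A3 (log2 1.78) and COL5A1 (0.87) rose, and COL15A1 (-1.97) and COL8A1 (-1.96) fell. COL5A1 scored 12136 with shLuc, 31936 with shMETTL3-1 and 15393 with shMETTL3-2 in both libraries, so its fold is a step between shared scores. The list did not pass camera (adjusted p = 0.705, and adjusted p = 0.828 with an estimated correlation). Its median of -0.24, its mean of -0.13 and the sign of camera were negative, while fry gave a positive sign (adjusted p = 0.0497). Collagen-processing enzymes had 13 of 20 lower, 6 higher and 1 not passing, again 13 and 6 adjusted over the list alone. SERPINH1, a collagen chaperone (-0.94), and LOXL1, a cross-linking oxidase (-1.93), fell, and LOXL2, a related oxidase (0.85), and COLGALT1, a collagen galactosyltransferase (0.43), rose. The list stood at the threshold without passing (adjusted p = 0.05, and adjusted p = 0.422 with an estimated correlation), and passed without shLuc replicate 1 (0.0454) or shMETTL3-1 replicate 2 (0.0424; range 0.0424 to 0.08). It also passed with no filter on low values (0.0496) and, in alternatives chosen after seeing the data, without genes under 10 (0.0488), without genes at the maximum (0.0496) and with pseudocounts of 10 (0.0496) and 50 (0.0482).

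Genes of stellate cell identity and quiescence did not move together: 4 of 14 were higher, 6 lower and 4 did not pass, as adjusted over the list alone. PLIN2, which coats lipid droplets, rose (log2 0.70), and NES, the intermediate filament nestin (-2.52), and ECM1 (-0.64) fell. HGF, hepatocyte growth factor, was called higher and was listed at 0 in both shLuc libraries, at 206 and 268 with shMETTL3-1 and at 322 and 286 with shMETTL3-2. The list did not pass camera (adjusted p = 0.47, and adjusted p = 0.648 with an estimated correlation). Its median was -0.17 and the sign of camera negative, while the mean of 0.32, which includes HGF, and fry were positive.

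For the TGF-beta pathway, 13 of 40 genes were higher, 17 lower and 10 did not pass, with 13 and 17 adjusted over the list alone. SNAI2, a transcriptional repressor (log2 2.16), and TGFBR2, the type II receptor (0.92), rose, and BMP4, a ligand of the family (-1.60), and the repressor ZEB2 (-1.37) fell. Camera did not pass it (adjusted p = 0.538, and adjusted p = 0.654 with an estimated correlation).

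LATS2, a kinase of the Hippo pathway that phosphorylates YAP (chromosome 13, 21547171 to 21635686), rose with shMETTL3-1 alone of the 2 hairpins. It scored 1218 and 1321 with shLuc, 2668 and 2815 with shMETTL3-1 and 1134 and 1138 with shMETTL3-2, a log2 change of 1.11 (adjusted p = 9.19e-06) and of -0.16 (adjusted p = 0.0556). The difference between the hairpins was -1.27 (adjusted p = 4.29e-06). YAP1 rose with both (0.30 and 0.60). Of 28 tested Hippo components 10 were higher, 11 lower and 7 did not pass, with the same 10 and 11 adjusted over the list alone. VGLL4, a competitor of YAP for TEAD factors, rose in the mean (1.03), and TAOK1, an upstream kinase (-0.77), and TEAD1, a DNA-binding partner of YAP (-0.63), fell. As a list they did not pass (adjusted p = 0.68, and adjusted p = 0.793 with an estimated correlation).

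Target genes of YAP and TAZ fell as a group. Of 34 tested 23 were lower, 7 higher and 4 did not pass, or 23 and 8 adjusted over the list alone (camera adjusted p = 0.00085; adjusted p = 0.353 with an estimated correlation). CTGF, a matricellular protein also named CCN2, fell with both hairpins (log2 -1.77 and -0.41), as did EDN1, the vasoconstrictor endothelin-1 (-1.72 in the mean). FJX1 rose in the mean (0.71), and LATS2 is on this list too. With both hairpins 12 members were lower and 2 higher, and 4 were called in opposite directions.

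Mitotic genes fell in the mean, with the smallest p of camera at the preset correlation among the 33 lists, whereas with an estimated correlation and with fry contractile genes had the smallest. Of 63 tested 48 were lower, 3 higher and 12 did not pass, or 49 and 4 adjusted over the list alone (camera adjusted p = 1.36e-07; adjusted p = 0.422 with an estimated correlation). AURKB, a mitotic kinase (log2 -0.92), and CDCA8, its partner in the chromosomal passenger complex (-0.79), fell. MKI67, the proliferation marker, fell with shMETTL3-1 (-0.59) and had a change of -0.14 with shMETTL3-2 (adjusted p = 0.124; difference 0.45, adjusted p = 0.00126). CDKN1A, the cell cycle inhibitor p21, rose with shMETTL3-1 (0.80) and had a change of -0.13 with shMETTL3-2 (adjusted p = 0.0912), and the hairpins differed by -0.93 (adjusted p = 1.28e-05). BUB3, a checkpoint protein, rose in the mean (0.31), as did ANLN, a cytokinesis protein (0.38, adjusted p = 0.022). ANLN did not pass without shLuc replicate 2 (log2 0.22) or shMETTL3-1 replicate 1 (0.36). Replication genes went both ways, with 17 of 54 higher, 16 lower and 21 not passing, as adjusted over the list alone. PCNA, the sliding clamp of DNA polymerases, rose (0.68), and CDC6, which loads the replicative helicase (-0.92), and UHRF1 (-0.93) fell. Camera gave an adjusted p of 0.927 for these genes (adjusted p = 0.928 with an estimated correlation), and their median of 0.02 and mean of -0.08 differed in sign.

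Autophagy and lysosome genes rose: 26 of 37 were higher, 5 lower and 6 did not pass, as adjusted over the list alone (camera adjusted p = 5.3e-05; adjusted p = 0.213 with an estimated correlation). ULK1, the kinase that starts autophagy (log2 1.12), and NEU1, a lysosomal sialidase (0.91), rose, and LAMP2 (-0.47) and CTSZ (-0.48) fell. With both hairpins 21 members were higher and 5 lower, and 2 were called in opposite directions.

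Genes of the inflammatory NF-kB response rose, 25 of 36 being higher and 5 lower while 6 did not pass, as adjusted over the list alone (camera adjusted p = 0.000261; adjusted p = 0.422 with an estimated correlation). With shMETTL3-1 alone 16 were higher and 8 lower (camera adjusted p = 0.445). The chemokine genes IL8 (log2 1.36) and CXCL1 (2.31) rose, and IL11 (-0.62) and TNFAIP2 (-0.43) fell. Interferon-stimulated genes had 30 of 46 higher, 5 lower and 11 not passing, or 30 and 6 adjusted over the list alone (camera adjusted p = 0.00085; adjusted p = 0.648 with an estimated correlation). With shMETTL3-1 alone 12 were higher and 10 lower, with a median of -0.03 (camera adjusted p = 0.966). HERC6 (2.00) and IFIT2 (2.28) rose, and the guanylate-binding proteins GBP1 (-1.97) and GBP2 (-1.24) fell.

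Stress and sterol genes rose in the mean of both hairpins but did not pass as lists with shMETTL3-1 alone. For the unfolded protein and ATF4 responses 26 of 42 were higher, 9 lower and 7 did not pass, or 27 and 10 adjusted over the list alone (camera adjusted p = 0.0219; adjusted p = 0.422 with an estimated correlation). With shMETTL3-1 17 were higher and 12 lower (camera adjusted p = 0.707), and the list did not differ between the hairpins past the threshold (camera adjusted p = 0.124). TRIB3, a pseudokinase induced by ATF4 (log2 1.41), and SLC7A11, the cystine transporter (1.98), rose, and SLC7A5, an amino acid transporter (-1.24), and SHMT2, a serine-metabolizing enzyme (-0.56), fell. For cholesterol synthesis 16 of 29 were higher, 4 lower and 9 did not pass, as adjusted over the list alone (camera adjusted p = 0.0219; adjusted p = 0.648 with an estimated correlation). With shMETTL3-1 7 were higher and 13 lower, with a median of -0.07 (camera adjusted p = 0.482), and 11 members were called in opposite directions with the 2 hairpins. FDPS (1.08) and HMGCS1 (0.71), enzymes of the mevalonate route, rose, and STARD4, a sterol carrier (-1.46), and the cyclase LSS (-0.61) fell.

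Respiratory chain subunits had 34 of 75 higher, 13 lower and 28 not passing in the mean, or 35 and 13 adjusted over the list alone. NDUFC2 and ATP5F1 rose (log2 0.58 and 0.59), and ATP5J2 and ATP5E fell (-0.40 and -0.58), although ATP5J2 rose with shMETTL3-1 (0.36) and fell with shMETTL3-2 (-1.16). The list did not pass in the mean (adjusted p = 0.0669, and adjusted p = 0.648 with an estimated correlation), but did without shLuc replicate 2 (0.0383) or shMETTL3-1 replicate 2 (0.0424; range 0.0383 to 0.312). Glycolysis and hypoxia genes had 8 of 37 higher and 18 lower, with 11 not passing, as adjusted over the list alone (camera adjusted p = 0.173; adjusted p = 0.422 with an estimated correlation). EPAS1, a hypoxia-inducible factor (0.88), and EGLN1, an oxygen sensor (2.24), rose, and HK2, a hexokinase (-1.59), and NDRG1 (-1.45) fell. NRF2 targets and antioxidant genes had 13 of 29 higher, 10 lower and 6 not passing, or 14 and 10 adjusted over the list alone (camera adjusted p = 0.283; adjusted p = 0.654 with an estimated correlation). FTL, ferritin light chain, rose (1.42). TXNRD1, thioredoxin reductase, had a mean of -0.86 but fell with shMETTL3-1 (-2.03) and rose with shMETTL3-2 (0.30). MT1F, a metallothionein, fell in the mean (-0.80) and with shMETTL3-2 (-1.52), and lay at -0.08 with shMETTL3-1 (adjusted p = 0.55). Immediate-early genes had 18 of 34 higher, 13 lower and 3 not passing, as adjusted over the list alone (camera adjusted p = 0.562; adjusted p = 0.735 with an estimated correlation). BHLHE40 (1.69) and DUSP6 (1.38) rose, and the related phosphatases DUSP1 (-0.77) and DUSP2 (-1.59) fell.

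In the mean of both hairpins 10 of the 33 lists passed camera, 6 of them upward. With an estimated correlation limma's camera passed 0, and 3 lists had an unadjusted p under 0.05. With 3 residual degrees of freedom that version could hardly pass a list, so it does not decide between the calls. Fry, which asks only whether a list moves on balance in one direction, passed 28. Of the members named as examples of their lists in the mean, TAOK1, ZC3H13, ANLN, TPM1, SLC7A11, HMGCS1 and MT1F were called with shMETTL3-2 and not with shMETTL3-1, and BUB3, KIAA1429 and LATS2 the other way, and the hairpins differed for each of them. None of 12 further tested lists passed camera in any of the 4 contrasts.

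With shMETTL3-1 the largest rises were in CLDN1 (log2 4.58), HMGA2 (4.43), LCP1 (3.70), SLC4A4, a sodium bicarbonate cotransporter (3.58), and CAV2 (3.37). SLC4A4 scored 90 and 70 with shLuc, 973 and 947 with shMETTL3-1, and 144 and 124 with shMETTL3-2. The largest falls were in MAMDC2 (-7.55), TNC (-4.46, from the maximum), MSRB3, a methionine sulfoxide reductase (-4.38), SYNPO2 (-4.10) and NPPB (-4.06). In all, 7281 genes were called, 3757 higher and 3524 lower.

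Mitotic genes fell with this hairpin, with 51 of 63 lower and 2 higher, or 53 and 2 adjusted over the list alone (camera adjusted p = 1.98e-09; adjusted p = 0.381 with an estimated correlation). Contractile genes fell as well, 18 of 25 lower and 1 higher, as adjusted over the list alone (camera adjusted p = 1.03e-05; adjusted p = 0.381 with an estimated correlation). YAP and TAZ targets had 20 of 34 lower and 9 higher, as adjusted over the list alone (camera adjusted p = 0.0135; adjusted p = 0.381 with an estimated correlation). Autophagy genes had 21 of 37 higher and 7 lower, as adjusted over the list alone (camera adjusted p = 0.0177; adjusted p = 0.381 with an estimated correlation). Of the 33 lists 5 passed with shMETTL3-1, 2 of them upward.

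With shMETTL3-2 the largest rises were in MMP1 (log2 6.88), CLDN1 (5.06), the chemokine CXCL5 (4.22), HMGA2 (3.87) and SERPINB2, an inhibitor of plasminogen activators (3.87). MMP1 scored 68 and 61 with shLuc, 392 and 286 with shMETTL3-1, and 8681 and 6822 with shMETTL3-2 (chromosome 11, 102660651 to 102668891). The largest falls were in AIF1L (-4.07), THRB, a thyroid hormone receptor (-4.04), ITGB3 (-3.74), PLCB4, a phospholipase C (-3.63), and TPPP3, a tubulin-binding protein (-3.57). In all, 7400 genes were called, 3828 higher and 3572 lower.

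Inflammatory, interferon and sterol genes rose with this hairpin. Interferon-stimulated genes had 34 of 46 higher and 6 lower, as adjusted over the list alone, with a median of 0.99 (camera adjusted p = 1.2e-05; adjusted p = 0.559 with an estimated correlation). NF-kB genes had 25 of 36 higher and 3 lower, as adjusted over the list alone (median 0.97; camera adjusted p = 1.72e-05; adjusted p = 0.317 with an estimated correlation). Sterol genes had 23 of 29 higher and 2 lower, or 24 and 2 adjusted over the list alone (median 0.80; camera adjusted p = 8.77e-06; adjusted p = 0.384 with an estimated correlation). HMGCS1, which makes HMG-CoA, rose by 1.47. Autophagy genes had 27 of 37 higher and 5 lower, as adjusted over the list alone (camera adjusted p = 1.89e-05; adjusted p = 0.199 with an estimated correlation).

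Stress genes of the ATF4 and unfolded protein responses also rose with shMETTL3-2, 25 of 42 higher and 7 lower, as adjusted over the list alone (camera adjusted p = 0.00437; adjusted p = 0.317 with an estimated correlation). SLC7A11, which is also a target of NRF2, went from 668 and 667 to 9725 and 8417, against 812 and 725 with shMETTL3-1. NRF2 targets had 18 of 29 higher and 6 lower, or 19 and 6 adjusted over the list alone (camera adjusted p = 0.00691; adjusted p = 0.48 with an estimated correlation). Respiratory chain genes had 36 of 75 higher and 9 lower, or 37 and 9 adjusted over the list alone (camera adjusted p = 0.0129; adjusted p = 0.532 with an estimated correlation). This last call was lost with the trend on transcript length removed, an alternative chosen after seeing the data (0.155; range 0.00777 to 0.155).

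Contractile genes fell with shMETTL3-2, with 20 of 25 lower and 2 higher, or 21 and 2 adjusted over the list alone (camera adjusted p = 8.77e-06; adjusted p = 0.199 with an estimated correlation). Matrix glycoproteins had 21 of 36 lower and 6 higher, as adjusted over the list alone (camera adjusted p = 0.00301; adjusted p = 0.317 with an estimated correlation). Collagen-processing enzymes had 12 of 20 lower and 4 higher, or 13 and 4 adjusted over the list alone (camera adjusted p = 0.0147; adjusted p = 0.317 with an estimated correlation). Mitotic genes had 30 of 63 lower and 6 higher, as adjusted over the list alone (camera adjusted p = 0.00156; adjusted p = 0.487 with an estimated correlation). YAP and TAZ targets had 18 of 34 lower and 5 higher, or 19 and 5 adjusted over the list alone (camera adjusted p = 0.00801; adjusted p = 0.317 with an estimated correlation). Glycolysis and hypoxia genes had 23 of 37 lower and 9 higher, as adjusted over the list alone (camera adjusted p = 0.0149; adjusted p = 0.317 with an estimated correlation).

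**Figure D2:**
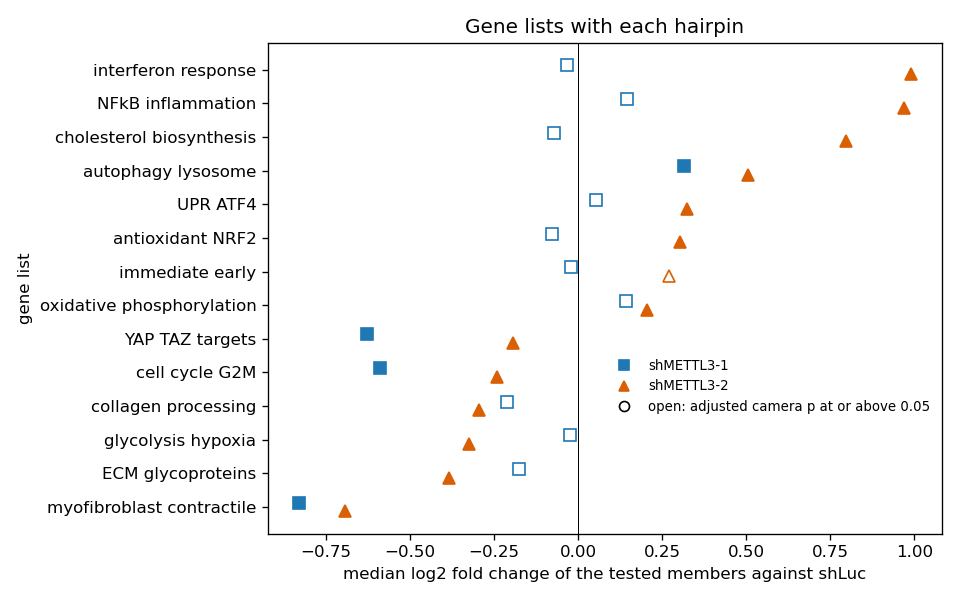
Median log2 fold change of the tested members of each gene list against shLuc with shMETTL3-1 (squares) and shMETTL3-2 (triangles), for the reported lists that passed camera in any contrast, with filled symbols where the list passed with that hairpin. Contractile genes lay at -0.83 and -0.69, whereas sterol genes lay at -0.07 with shMETTL3-1 and 0.80 with shMETTL3-2.

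The comparison of the 2 hairpins asks whether they had the same effect. SERPINB2 was the ranked gene most raised with shMETTL3-2 relative to shMETTL3-1 (log2 5.87), with scores of 37 and 30 against 1988 and 2012. MAMDC2 (4.76), MMP1 (4.52), C1GALT1C1, a chaperone of O-glycosylation (3.96), and MYLIP, a ubiquitin ligase for the LDL receptor (3.95), followed. EDA2R, a receptor of the TNF receptor family, was the most lowered (-4.61), with scores of 490 and 480 against 20 and 18. PLAU, urokinase (-4.35), TES, a focal adhesion protein (-4.15), PGK1, a glycolytic kinase (-4.06), and RRM2B, a ribonucleotide reductase subunit (-3.71), were lower as well. In this contrast 7824 genes were called, 3962 higher and 3862 lower with shMETTL3-2.

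By list, interferon-stimulated genes had 34 of 46 higher and 5 lower, or 35 and 5 adjusted over the list alone (camera adjusted p = 3.07e-06; adjusted p = 0.552 with an estimated correlation). Sterol genes had 23 of 29 higher and 2 lower, as adjusted over the list alone (camera adjusted p = 3.07e-06; adjusted p = 0.491 with an estimated correlation). Mitotic genes had 35 of 63 higher and 6 lower, or 36 and 6 adjusted over the list alone (camera adjusted p = 0.00167; adjusted p = 0.491 with an estimated correlation). NF-kB genes had 25 of 36 higher and 6 lower, or 27 and 6 adjusted over the list alone (camera adjusted p = 0.0023; adjusted p = 0.491 with an estimated correlation). NRF2 targets had 20 of 29 higher and 7 lower, as adjusted over the list alone (camera adjusted p = 0.00809; adjusted p = 0.491 with an estimated correlation). Immediate-early genes had 22 of 34 higher and 7 lower, as adjusted over the list alone (camera adjusted p = 0.0278; adjusted p = 0.491 with an estimated correlation). The last call was lost without shMETTL3-1 replicate 1 (0.0525; range 0.0136 to 0.0525).

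The genes changed by both hairpins in the same direction numbered 3610, 1949 higher and 1661 lower, where independent lists of these sizes would share 1159 and 1014. A further 1309 genes were called in opposite directions, 676 of them higher with shMETTL3-1 (1081 for independent lists) and 633 lower (1087). These are 26.6% of the 4919 genes called with both hairpins, and all 1309 were also called in the direct comparison of the hairpins. Both contrasts use the same shLuc libraries, which alone makes them correlate. Across genes, which are not independent replicates, the log2 changes correlated at 0.469 and 62.5% had the same sign. Simulated unchanged groups with shared controls gave 0.492 and 66.7%. These 2 simulated values follow from groups of equal size that share controls, whatever the spread. Setting them beside the observed values therefore does not decide whether the hairpins agree. The variances across genes were 0.716 and 0.778, against a simulated 0.1388. The covariance was 0.35 against a simulated 0.0685, a difference of 0.281, and simulated groups shared 0.16 called genes on average. Without genes with a value under 10 the difference in covariance was 0.198. The difference leaves out only the simulated covariance of shared controls. The 2 controls were not split, since each hairpin would then have 1 control library, so part of the excess of shared calls over independent lists may come from the shared libraries.

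The rule for named genes, applied as written, picked mostly genes near the floor, which are given here as listed scores. TNFSF13B, a B-cell cytokine, was listed at 0 in both shLuc libraries, at 218 and 304 with shMETTL3-1 and at 324 and 316 with shMETTL3-2. CGA, a hormone subunit, was listed at 0 in both shLuc libraries and between 255 and 319 in the hairpin libraries. CSMD3, ADAM29 and SNORA59B were likewise listed at 0 with shLuc and between 156 and 226 with the hairpins. PDK4, a kinase that inhibits pyruvate dehydrogenase, was listed at 262 and 182 with shLuc and at 0 in all 4 hairpin libraries, and RBM11 at 207 and 178 and then at 0. Genes listed at 0 in one library can stand far above it in the replicate: RSPO3 was at 0 and 169, and VIP at 226 and 0, in the shMETTL3-1 libraries. The other genes under 10 in some library that this rule picked were TFEC, LINC00704, ZBBX, DCDC1, CXCL11, SLCO1A2, GPR65, MYOZ2, AGMO, CFHR4, CRB2, ALPP, KLHL30, A1CF, ZNF385D, SPATA17, CD200R1, HTN1, FSTL5 and ANKRD20A4. Genes like these make up 44 of the 50 places of the rule, 41 of them with a 0.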

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

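The tests of the difference between hairpins were planned, whereas the tests on depth of METTL3 loss and on the transcript length trend were chosen only after the results were seen. Each result below is singled out because the direct test of shMETTL3-2 against shMETTL3-1 passed. Since that test is also a comparison of the report, only gene lists and the genes chosen in advance are given singly. Groups of 2 libraries are too small to look for a library far from the others.

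By list, the median log2 difference (shMETTL3-2 minus shMETTL3-1) was 1.04 for cholesterol synthesis, 1.00 for interferon-stimulated genes, 0.59 for NF-kB genes, 0.45 for NRF2 targets, 0.35 for immediate-early genes and 0.30 for mitotic genes. These calls rest on the preset correlation, and with an estimated correlation the smallest adjusted p of this contrast was 0.491. The call for immediate-early genes was lost without shMETTL3-1 replicate 1 (adjusted p = 0.0525; range 0.0136 to 0.0525).

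Of the 16 genes chosen in advance, 13 differed between the hairpins. Lower with shMETTL3-2 were LATS2 (log2 -1.27), CDKN1A (-0.93), METTL3 itself (-0.92) and TGFB1 (-0.31). COL1A1 was lower too, but it stood at the shared maximum with shMETTL3-1, so its value of -0.71 is truncated and gives no measured size. Higher with shMETTL3-2 were TIMP1 (1.85), COL3A1 (1.40), CTGF (1.36), PDGFRB (0.99), COL1A2 (0.78), ACTA2 (0.65), MKI67 (0.45) and YAP1 (0.30).

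About as many genes differed between the hairpins (7824) as between a hairpin and shLuc (7281 and 7400). If shMETTL3-2 only deepened the effect of shMETTL3-1, the effects should correlate closely without replicate error and shared controls. Once their simulated values were subtracted, the correlation was 0.463 (0.436 to 0.489 without any 1 library). The changes in the 2 hairpin groups were thus not multiples of each other. A difference between the cultures or infections of the groups is not subtracted and would also lower the correlation. The value therefore cannot exclude deeper METTL3 loss. A trend on transcript length is not the whole cause of the differences. Of the genes that differed and had a transcript length, 94.4% kept their call after the trend was removed. That is 93.3% of all 7824, 96 of which had no length and were not tested. Effects of each hairpin on transcripts other than METTL3 stay open and could not be tested with 1 control hairpin. Differences between the cultures or infections of the groups stay open too and cannot be told apart from the hairpin.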

How the results depend on the processing

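The pseudocounts of 10 and 50, leaving out genes with a value under 10 or at the maximum, and removing the length trend were chosen after the results were seen, and the other alternatives were planned. The planned DESeq2 test and TMM scaling with edgeR were not run, since the values are not counts. METTL3 stayed lower in every setting, its mean log2 change running from -1.54 to -1.28, and with both hairpins as one group its adjusted p was 0.0496. The values do not keep depth, so its limits could not be examined.

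A 2-fold threshold beside the adjusted p left 1498 genes for shMETTL3-1, 1573 for shMETTL3-2, 1043 for their mean, 481 for both hairpins and 1832 between the hairpins; fewer genes follow from its construction. With both hairpins as one group 1494 genes were called in the mean, where the difference between hairpins adds to the spread. Of the lists in the mean, 10 passed with the preset correlation, 0 with an estimated one and 28 with fry, which asks another question.

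Without any 1 library (the group left with 1 library is assumed to vary like the others) the counts ran from 5746 to 7436 for shMETTL3-1, 6364 to 6965 for shMETTL3-2, 5882 to 7126 for the mean, 2962 to 3436 for both hairpins and 6377 to 7763 between hairpins. Lists passing in the mean ran from 9 to 13, and METTL3 from -1.54 to -1.45. Under the remaining settings the counts ran from 7194 to 7698, 6969 to 7769, 7165 to 7641, 3506 to 3896 and 7662 to 8196 in the same order, and the lists from 8 to 11.

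Lists were not rerun with voom weights, with only the groups compared or with both hairpins as one group. Of 1344 list results over the other alternatives 1260 kept their side of the threshold, 42 lost and 42 gained a call. Of 2249 results of named genes 2186 kept it, 62 lost and 1 gained, 56 of the losses being with both hairpins as one group. No result called in the main fit reversed its direction. Results not called there could change sign, as collagen chains in the mean did with fry. The replicate numbers share only a number between groups, and deviations from the group mean correlated at 0.015 (shLuc and shMETTL3-1), 0.037 (shLuc and shMETTL3-2) and 0.047 (both hairpins), or at 0.059, 0.182 and 0.004 over 12188 genes with no value under 10. With a replicate block added, 7698, 7769, 7641, 3896 and 8196 genes were called and 10 lists passed.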

Other observations

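The genes in this part were chosen after their values were seen, and the test on GC content was chosen only after the pattern was seen. Proteases that degrade matrix and their inhibitors went both ways. MMP9, a gelatinase, rose by log2 2.14 and 1.69 with shMETTL3-1 and shMETTL3-2, MMP14, a membrane-bound collagenase, by 1.87 and 0.84, whereas MMP15, another membrane-bound metalloproteinase (-0.81 and -0.88), and ADAMTS1 (-0.97 and -0.39) fell with both. RECK, a membrane-anchored inhibitor, rose by 1.10 and 1.70, and TIMP3, another inhibitor, fell by 1.81 and 1.49 on the log2 scale. The urokinase system split by hairpin: PLAU rose with shMETTL3-1 (1.70) and fell with shMETTL3-2 (-2.65), and its receptor PLAUR did the reverse (-0.75 and 1.25). Of 23 tested proteases and inhibitors 9 were higher in the mean, 7 lower and 7 did not pass, as adjusted over the list alone, and 6 were called in opposite directions with the 2 hairpins. The list did not pass camera (adjusted p = 0.68, and adjusted p = 0.735 with an estimated correlation).

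Integrins and focal adhesion genes went both ways. ITGA2, a collagen-binding integrin subunit, rose with both hairpins (2.74 and 2.98), as did the laminin-binding ITGA6 (0.93 and 0.95) and the hyaluronan receptor CD44 (1.10 and 0.36). ITGA7, another laminin receptor, fell (-1.44 and -0.85) along with ITGB3, and CAV1 rose with shMETTL3-1 (0.52) and fell with shMETTL3-2 (-1.72). Of 34 tested 9 were higher, 15 lower and 10 did not pass, as adjusted over the list alone (camera adjusted p = 0.36; adjusted p = 0.648 with an estimated correlation). Among genes of MHC class I, B2M, the light chain, fell by 0.67 and 1.05 on the log2 scale. NLRC5, the class I transactivator, fell by 1.42 and 1.22, while ERAP2, a peptide-trimming protease, rose (1.81 and 1.29). With both hairpins 4 members were lower and 3 higher. Of 14 tested 8 were lower, 3 higher and 3 did not pass, as adjusted over the list alone (camera adjusted p = 0.224; adjusted p = 0.648 with an estimated correlation).

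Markers of other liver cell types gave few values. Of hepatocyte markers 1 of 5 was higher in the mean, 1 lower and 3 did not pass, or 1 and 2 adjusted over the list alone (camera adjusted p = 0.68; adjusted p = 0.735 with an estimated correlation). Of endothelial markers 2 of 6 were higher, 2 lower and 2 did not pass, as adjusted over the list alone (camera adjusted p = 0.927; adjusted p = 0.928 with an estimated correlation). Cholangiocyte markers had 2 of 4 higher and 1 lower, and macrophage and leukocyte markers 1 of 4 higher and 0 lower, both too few to test. The higher one was CD68, a lysosomal glycoprotein, at log2 1.51 in the mean. The deposited table used here held 3 of the 79 listed ribosomal protein genes and 0 of the listed mitochondrial genes, so neither group was described.

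Within each library the highest values come in groups of about 10 genes with one score. When genes were linked by sharing a score above 5000, 724 genes formed 7 groups, whose median GC content ran from 39% to 58.5%. These groups held 54.2% of the variance in GC content, against at most 3.1% in 1000 shuffled groupings. Normalization within classes of genes of like GC content is a candidate explanation, as a hypothesis only. If it holds, a score ranks a gene among others of like GC content, and levels of genes of different GC content are not on one scale.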
